A study of Homo sapiens with 17 samples.

How the data were processed

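The series profiled THP-1, an established human monocytic leukaemia line used as a model of monocytes, after transfection of plasmid DNA (pDNA) with the reagent TransIT-2020. A time course of 12 bulk RNA-seq libraries held 4 conditions at 12, 24 and 36 h, with 1 library per condition and time. The conditions were a negative control (NC) given DMSO and transfection reagent only, 1 µM H151, 3 µg pDNA, and pDNA together with H151. H151 is a small-molecule inhibitor of STING, the adaptor that relays the signal of the DNA sensor cGAS. In a separate experiment, cells were sorted by GFP fluorescence 12 h after transfection of 3 µg pDNA, with 2 GFP-negative and 2 GFP-positive libraries labelled as biological replicates. A single-cell RNA-seq library was made 12 h after transfection of 2 µg and 4 µg pDNA; the labels give no map from cells to amounts, so it was treated as 1 sample.

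Bulk RNA was isolated with TRIzol and prepared with a TruSeq total RNA kit, per the labels, whereas the molecule field of the labels reads polyA RNA. The bulk values were raw counts per Ensembl gene deposited by the authors in 1 table of 61860 genes. HISAT2 2.2.0, SAMtools 1.15.1, featureCounts 2.0.1 and the build hg38 are listed in the submitters' processing notes; the annotation, the strand setting and any filters were not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore not be told apart, and the replication-dependent histone genes, which have close paralogs, are uncertain as single genes. The single-cell values were UMI counts per gene and barcode as deposited by the authors, 7137 barcodes by 20024 features with an added EGFP feature. Cell Ranger 7.1.0 stands in the submitters' processing notes and an earlier release in the matrix header. Gene symbols came from the single-cell feature list for 19401 IDs and from a gene name table for 42359, which left 100 without a symbol. Coordinates were taken from GENCODE 29 on GRCh38, which held 58308 of the IDs. All columns of the deposited count table were used.

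Totals ran from 16886430 to 27361119 counts per bulk library. None of the 120 pairs of libraries held identical values, and the sorted replicates differed by more than sampling noise (chi-square per degree of freedom 131 for GFP-negative and 57.3 for GFP-positive). Nothing in the labels says that the time-course libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The spread of the time course holds library noise together with any departure from a constant effect over time.

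The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The main test was edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr and robust quasi-likelihood F-tests, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 12 time-course libraries entered 1 fit with condition and time as factors (19173 genes). From it came pDNA versus NC, pDNA with H151 versus H151, pDNA with H151 versus pDNA, H151 versus NC, the interaction of pDNA and H151, and, with an added term, a linear trend of the pDNA effect per 12 h shared by both pDNA arms. The 4 sorted libraries had their own fit (16656 genes). Log2 fold changes are fitted values with an approximate standard error (±), with 3 libraries per condition in the time course and 2 per group in the sorted cells. This error is the absolute log2 fold change over the square root of the F statistic. Ratios at a single time have no replicate and no test. Bulk levels are CPM with library sizes scaled by TMM.

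In all, 23 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation; fry was run beside them and is given with the alternatives. Members past the threshold were counted over all genes tested and adjusted over the list alone. The named genes were, per comparison, the 6 highest and the 6 lowest called genes with a mean of 1 CPM or more and the same direction at each time or pair, up to 3 called members per list, and a fixed panel of 30 genes. Where a group held no count of a gene, its fold was bounded against 3 counts over the group; with 1 to 3 counts the pooled ratio is given with its exact 95% interval, which covers counting error only.

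On simulated counts with 100 genes changed at each size, the test recovered 47% of 2-fold and 85% of 4-fold changes for pDNA versus NC (19173 genes), 18% and 71% for the interaction, 58% and 95% for the trend, and 6% and 62% for the sorted cells (16656 genes). It called 2, 2, 8 and 3 unchanged genes in these comparisons. Each time the changed list was called and 0 of 22 unchanged lists were. The simulated genes were drawn independently of each other, so the list result says nothing on camera where genes of a list vary together.

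Single cells were kept with 500 or more genes and at most 20% mitochondrial UMIs, which left 6128 of 7137 barcodes with a median of 28880 UMIs and 5443 genes. Shares of cells with a UMI have exact (Clopper-Pearson) binomial intervals that cover counting error only, and are given unthinned and after thinning each cell to 6303 UMIs, which left out 613 shallower cells. On simulated cells thinning reduced the largest gap between depths from 29.3% to 1.8%. Barcodes with fewer than 500 genes (754, median 731 UMIs) were used as background. Whether these were empty droplets or damaged cells was not known, so they need not show free RNA alone. Cells were clustered by the Leiden method in scanpy 1.11.5 (leidenalg 0.10.2, igraph 0.11.9; resolution 0.5, 2000 variable genes, 30 principal components, 15 neighbours). The doublet caller scrublet marked 1 cell (0.0163%), which is taken to mean that it did not work here, so doublets remained in the data. With 1 library there was no test between cells. Other versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

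The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter and a filter at 5 CPM, a minimum absolute log2 fold change of 1, no time term, fits of only the libraries compared, a fit of all 16 bulk libraries, each library and each time left out, a replicate block for the sorted cells, estimated correlations and ranks in the list tests, and other cell filters, thinning depths and clustering settings. Fits without the 24 h libraries labelled H151 and pDNA_H151, list tests with a block, and groups of cells by their EGFP UMIs were chosen after seeing the data.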

Results

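Gene expression was measured in THP-1 cells after entry of plasmid DNA into the cytosol, a trigger of the cGAS-STING pathway and of interferon production. The 16 bulk libraries held 16886430 to 27361119 counts each. The time course had 3 libraries (12, 24 and 36 h) in each of 4 conditions, which were NC, H151, pDNA and pDNA with H151. The sorted experiment had 2 GFP-negative and 2 GFP-positive libraries, and the single-cell library held 6128 kept cells with a median of 28880 UMIs. Errors written with ± after a log2 fold change are approximate standard errors derived from the F statistic of the edgeR test. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, or from camera for gene lists.

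The first comparison asked what pDNA changed relative to the transfection reagent alone. The pooled level of VCAM1, an endothelial and leukocyte adhesion molecule (chromosome 1, 100719742 to 100739045), was 702-fold that of NC (counting interval 240 to 3410, with 3 counts in NC; log2 fold change 9.32 ± 1.86, adjusted p = 0.0471). IL6, an inflammatory cytokine (chromosome 7, 22725884 to 22732002), was 323-fold higher (57.5 to 12800, with 1 count in NC; adjusted p = 0.0364). ACOD1, which makes itaconate in activated macrophages, was at least 63.7-fold higher than NC, where it had no count (adjusted p = 0.0355). Among genes with counts in both groups, BCL2A1, an anti-apoptotic NF-kB target, rose by 4.41 ± 0.79 (adjusted p = 0.0332), ICAM1 by 4.31 ± 0.84 (adjusted p = 0.0448) and IL1B by 2.68 ± 0.38 (adjusted p = 0.0137). CGAS, the DNA sensor itself (chromosome 6, 73413515 to 73452276), rose by 0.90 ± 0.17 (adjusted p = 0.0329). Genes that fell included CNR1, the cannabinoid receptor (-2.04 ± 0.29, adjusted p = 0.0189), and SLC24A4, a sodium, calcium and potassium exchanger (-2.32 ± 0.37, adjusted p = 0.0242). Each of these genes moved the same way at all 3 times.

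In all, 967 of 19173 genes passed the threshold, 619 higher and 348 lower, and 336 and 102 of them changed at least 2-fold. With upper-quartile scaling the split was 608 higher and 675 lower. The interferon-related genes IFNB1, CXCL10 and IFIT1 lay far apart between these conditions and did not pass this test over all genes. The log2 fold change was 8.95 ± 2.33 for IFNB1, which encodes interferon beta (chromosome 9, 21077105 to 21077963; adjusted p = 0.0724). It was 11.10 ± 3.42 for CXCL10, a chemokine induced by interferon (chromosome 4, 76021117 to 76023497; adjusted p = 0.102), and 7.33 ± 3.25 for IFIT1, an interferon-induced RNA-binding protein (chromosome 10, 89392546 to 89406486; adjusted p = 0.2). IFIT1 stood at 1.25, 2.28 and 10.6 CPM in NC and at 569, 698 and 541 CPM in pDNA at 12, 24 and 36 h. CXCL10 stood at 0.363, 0.395 and 0.476 CPM in NC and at 695, 1345 and 599.6 CPM in pDNA. The standard errors hold the spread of the H151 conditions, whose 24 h libraries are described further on. STING1 (-0.26 ± 0.09, adjusted p = 0.0895), TBK1 (0.39) and IRF3 (0.11), which relay the signal, did not pass. The count was set by single libraries. It was 7, 3 and 5 without the NC library of 12, 24 or 36 h, 224, 2382 and 1763 without that of H151, 2040, 4 and 22 without that of pDNA, and 343, 2905 and 1644 without that of pDNA with H151. Without all libraries of 12, 24 or 36 h it was 36, 1091 and 5. Of 30 named genes that passed, 0 passed when the NC library of any 1 time or the 24 h pDNA library was left out, 1 without the 36 h pDNA library, 7 without the 12 h H151 library and 14 without the 12 h library of pDNA with H151.

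By fixed list, 13 of 25 tested NF-kB targets and inflammatory cytokines rose (24 adjusted over the list alone; median log2 fold change 2.30; camera adjusted p = 3.14e-28, adjusted p = 0.241 with an estimated correlation). Of 17 immediate early genes 6 rose, among them EGR2 (2.46 ± 0.54), KLF4 (2.2 ± 0.41) and JUNB (1.59 ± 0.28), transcription factors made early after stimulation (15 adjusted over the list alone; median 1.46, adjusted p = 2.05e-12, adjusted p = 0.241 with an estimated correlation). None of the 46 interferon-stimulated genes passed singly, also adjusted over the list alone. All 46 had a positive fold change and the list was called higher (median 4.64, adjusted p = 2.97e-23, adjusted p = 0.244 with an estimated correlation). The 2 tested interferon ligands had a median of 9.13 (0 passed over all genes and 2 over the list alone; adjusted p = 0.00457), and the 6 tested interferon-induced chemokines a median of 8.83, or 8.18 with genes absent from NC at their bound (1 passed over all genes and 6 over the list alone; adjusted p = 4.36e-08; the 1 is CXCL9, at least 53.5-fold higher, adjusted p = 0.0413). Both had an adjusted p of 0.241 with an estimated correlation. Class I antigen presentation was higher in 17 of 17 members over the list alone and in 1, TAPBP (0.81 ± 0.16), over all genes (median 1.09, adjusted p = 1.54e-11, adjusted p = 0.244 with an estimated correlation). Translation and foreign RNA restriction genes had a median of 2.73 (adjusted p = 5.61e-10), monocyte and macrophage markers 1.22 (1.59e-06), inflammasome genes 0.92 (0.000373), class II genes 0.85 (0.0038), lysosome and autophagy genes 0.69 (2.18e-06), heat shock genes 0.46 (0.00653) and p53 targets 0.20 (0.00457). The adjusted p of these 7 lists was 0.241 to 0.394 with an estimated correlation. The list given as p53 targets, here and below, also holds apoptosis genes such as FAS and TNFSF10. The translation and foreign RNA restriction list shares IFIT and OAS members and EIF2AK2 with the interferon-stimulated list. Here and below it is therefore not a separate result. NPC1, the lysosomal cholesterol exporter, rose by 1.04 ± 0.13 (adjusted p = 0.00715), and FAS, a death receptor, by 2.29 ± 0.54 (adjusted p = 0.0448). S phase genes (median -0.18, adjusted p = 0.0194) and replication-dependent histones (-0.25, adjusted p = 0.0493) were lower as lists, at an adjusted p of 0.619 with an estimated correlation. The lists not called were cytosolic DNA sensing (median 0.10, adjusted p = 0.181), unfolded protein and integrated stress response (0.01, 0.941), G2 and M phase (-0.07, 0.264), cholesterol synthesis (0.14, 0.137), hypoxia and glycolysis (0.02, 0.646), foreign DNA silencing (-0.05, 0.93), mitochondrially encoded mRNAs (0.16, 0.646) and markers of other cell types (0.66, 0.226). Of the last, NKG7, a gene of cytotoxic lymphocytes, rose by 1.12 ± 0.26.

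**Figure D1:**
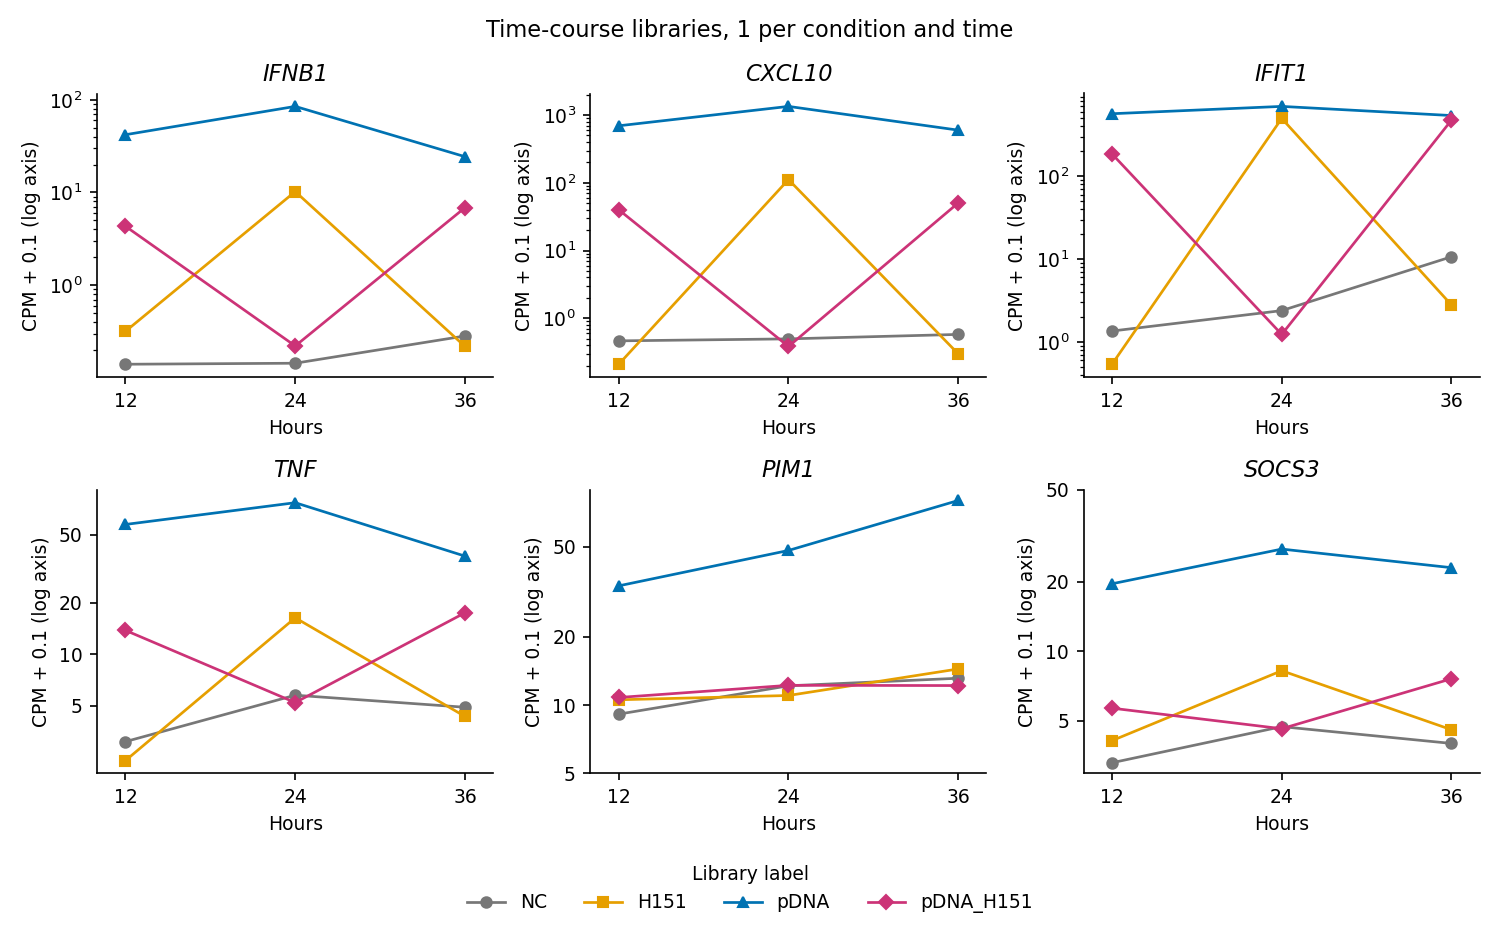
Level of 6 genes (CPM plus 0.1, log axis) against hours after transfection, with 1 library per condition and time, in the 4 conditions. IFIT1 stands at 499 CPM in the library labelled H151 24 h and at 1.13 CPM in the library labelled pDNA_H151 24 h, and PIM1 lies at 33.5 to 79.8 CPM in pDNA and at 10.7 to 12.1 CPM in pDNA with H151.

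At 24 h a pair of libraries stood apart from the others of their conditions. The library labelled H151 24 h, whose label gives no pDNA, held IFIT1 at 499 CPM, MX1, an antiviral GTPase, at 1946 CPM and IFNB1 at 10.1 CPM. The library labelled pDNA_H151 24 h held 1.13, 5.12 and 0.121 CPM of the same genes. The other H151 libraries had 0.436 and 2.69 CPM of IFIT1, and the other libraries of pDNA with H151 had 186 and 476 CPM. The median log2 ratio of the interferon-stimulated list in pDNA with H151 over H151 was 3.22, -5.08 and 4.65 at 12, 24 and 36 h, and in H151 over NC it was -0.03, 4.76 and -0.65. Every direction drawn from these libraries, here and for each list, carries this limit.

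Without this pair, a fit chosen after seeing the data (10 libraries, 19713 genes), interferon genes passed the test for pDNA versus NC. All 46 interferon-stimulated genes rose (median 4.68; adjusted p = 0.0177 with an estimated correlation), as did 3 of 3 ligands (8.89; 0.0209), 6 of 6 chemokines (8.80, or 8.17 with bounds; 0.00348), 24 of 26 NF-kB targets (2.42; 0.0185) and 17 of 19 translation restriction genes (0.0177). CXCL10 rose by 10.95 ± 0.23 (adjusted p = 1.63e-10), IFNB1 by 8.89 ± 0.51 (adjusted p = 2.01e-05) and IFIT1 by 7.39 ± 0.80 (adjusted p = 0.00633). IDO1, the tryptophan-degrading enzyme, rose by 10.89 ± 0.70. Over the alternatives the adjusted p ranged from 1.63e-10 to 0.373 for CXCL10, from 2.95e-06 to 0.295 for IFNB1 and from 0.00323 to 0.456 for IFIT1. CXCL10 and IFNB1 each passed in 6 of 24 alternatives and IFIT1 in 4. Settings fixed beforehand were among them, so these calls do not rest only on the fit without this pair. In this fit 3247 genes passed, and the 967 genes of the full fit were all among them.

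Adding H151 to pDNA addressed which part of the response the inhibitor lowered. PIM1, a serine/threonine kinase induced by cytokine signalling (chromosome 6, 37170203 to 37175426), fell by 2.13 on the log2 scale (± 0.18, adjusted p = 0.000689) relative to pDNA alone. Its level was 33.5, 48 and 79.8 CPM in pDNA and 10.7, 12.1 and 12.1 CPM in pDNA with H151, where NC had 9.03, 12.1 and 13. SOCS3, the feedback inhibitor of cytokine receptors (chromosome 17, 78356778 to 78360077), fell by 1.96 ± 0.24 (adjusted p = 0.0174). The somatostatin receptor SSTR2 (-3.08 ± 0.42, adjusted p = 0.0288), the G-protein regulator RGS16 (-1.71 ± 0.21, 0.0264), the proteoglycan SDC4 (-1.23 ± 0.17, 0.0316) and the autophagy gene VMP1 (-0.99 ± 0.12, 0.0174) also fell. These 6 genes were the only ones that passed in this fit, and all were lower at each of 3 times. The 24 h pair bears on which genes could pass here. In the libraries labelled H151 24 h and pDNA_H151 24 h, PIM1 stood at 10.9 and 12.1 CPM, but CXCL10 at 112 and 0.282 CPM. The 6 genes are therefore not the whole of what H151 lowered, as the fit without the pair below shows. DESeq2 called 476 genes, 163 higher and 313 lower, and limma-voom 4, all lower. With no filter 158 passed, 60 higher and 98 lower.

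By list, NF-kB targets had a median of -1.49 (18 of 25 lower adjusted over the list alone, 0 over all genes; camera adjusted p = 9.25e-25, adjusted p = 0.305 with an estimated correlation). Chemokines had -4.10 (3 of 6 over the list alone; adjusted p = 2.93e-07 and 0.305 with an estimated correlation), ligands -3.59 (0.0295 and 0.43), immediate early genes -1.02 (7 of 17 over the list alone; 6.51e-10 and 0.305) and interferon-stimulated genes -1.29 (0 of 46 by either count; 1.64e-09 and 0.55). Class I genes (-0.73), translation restriction genes (-1.07), monocyte markers (-0.72), inflammasome genes (-0.58), lysosome genes (-0.41), mitochondrially encoded mRNAs (-0.38) and p53 targets (-0.23) were lower as lists too, each at an adjusted p of 0.305 to 0.55 with an estimated correlation. Mitochondrially encoded mRNAs took at most 0.0601% of counts in any time-course library, which limits that list. The median of the interferon-stimulated list was -1.44 at 12 h, -5.52 at 24 h and -0.26 at 36 h, and that of the chemokines -3.28, -7.75 and -3.37, where the 24 h value rests on the library labelled pDNA_H151 24 h. Without the 24 h pair 67 genes were lower, including all 6 above. CXCL10 fell by 3.90 ± 0.19 (adjusted p = 1.23e-06), CCL8, a monocyte chemoattractant, by 3.58 ± 0.28 (0.000823), IDO1 by 4.39 ± 0.51 (0.012) and IFNB1 by 2.61 ± 0.38 (0.0471), with 4 of 6 chemokines (adjusted p = 0.000772 with an estimated correlation), 10 of 26 NF-kB targets (0.0274) and 0 of 46 interferon-stimulated genes (3 adjusted over the list alone; median -0.95; 0.131). Over the alternatives the adjusted p ranged from 1.23e-06 to 0.848 for CXCL10 and from 0.0458 to 0.814 for IFNB1. The count was 1 without the 24 h NC or the 24 h pDNA library, 2 without pDNA 36 h, 3 without the 12 h or the 36 h library of pDNA with H151, 46 without H151 24 h (4 higher) and 345 without pDNA 12 h (156 higher, 189 lower). It was 42 without all 24 h and 2 without all 36 h libraries. PIM1 still passed when any 1 library was left out and did not pass in the fit of 6 libraries (adjusted p = 0.0747). SOCS3 did not pass without NC 24 h, pDNA 24 h or 36 h, or pDNA with H151 12 h (0.0603 to 0.178). SSTR2, RGS16, SDC4 and VMP1 did not pass without NC 24 h, pDNA 24 h or pDNA with H151 12 h either (0.0603 to 0.272). Without pDNA 36 h SSTR2 (0.24), SDC4 (0.221) and VMP1 (0.115) did not pass, without pDNA with H151 36 h SSTR2 (0.0585), RGS16 (0.0622) and SDC4 (0.0852), and without pDNA with H151 24 h SSTR2 (0.134) and SDC4 (0.137). SDC4 also failed without NC 36 h (0.0788) or H151 12 h (0.0608). Without all libraries of 12, 24 or 36 h, 2, 4 and 1 of the 6 genes passed.

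The effect of pDNA in the presence of H151 was tested against H151 alone. Over all 12 libraries edgeR called 0 genes, with 292 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The interferon-stimulated list was called higher with a median of 0.83 (adjusted p = 1.49e-05), as were NF-kB targets (0.41, 7.61e-05), translation restriction genes (0.55, 0.00143), cholesterol synthesis (0.10, 0.00175), heat shock (0.20, 0.00648) and immediate early genes (0.19, 0.0255), while histones were lower (-0.26, 0.000401). All had an adjusted p of 0.772 or 0.773 with an estimated correlation, and the medians mix unlike values over time. The sign at 24 h was opposite to that at 12 and 36 h for interferon-stimulated genes, NF-kB targets, translation restriction genes, heat shock and immediate early genes, while cholesterol synthesis stood at 0.22, 0.00 and 0.16 and histones at 0.07, -0.04 and -0.72 at 12, 24 and 36 h. Without the 24 h pair 255 genes passed, 252 of them higher, and without all 24 h libraries 222. MX1 rose by 6.86 ± 0.65 (adjusted p = 0.0176), CXCL10 by 8.15 ± 0.31 (1.24e-07) and IFNB1 by 4.96 ± 0.63 (0.00862). Of the interferon-stimulated list 31 of 46 rose (46 adjusted over the list alone; median 4.08; adjusted p = 0.00962 with an estimated correlation), with 2 of 3 ligands (0.0393), 4 of 6 chemokines (0.00714), 11 of 19 translation restriction genes (0.00962) and 9 of 26 NF-kB targets (14 over the list alone; median 1.09; 0.0522). Over the alternatives the adjusted p ranged from 1.24e-07 to 1 for CXCL10 and from 0.00562 to 1 for IFNB1.

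H151 alone was compared with NC. EdgeR called 0 genes (193 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 3. Of the 23 lists 13 were called, led by interferon-stimulated genes (median 2.46, adjusted p = 6.68e-14, adjusted p = 0.572 with an estimated correlation), whose level rests on the library labelled H151 24 h. Without the 24 h pair 0 genes passed (169 at an unadjusted p under 0.05) and that list had a median of -0.27 (camera adjusted p = 9.55e-13, adjusted p = 0.946 with an estimated correlation).

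The interaction compared the pDNA effect with and without H151. PIM1 was the only gene that passed, with a pDNA effect lower by 2.2 ± 0.25 on the log2 scale under H151 (adjusted p = 0.019; 0.212 by limma-voom; DESeq2 called 148 genes). It did not pass when any 1 of the NC libraries (0.108 to 0.161), H151 12 h (0.135), pDNA 24 h (0.11) or pDNA with H151 12 h (0.0541) was left out. Over its alternatives the adjusted p ranged from 2.22e-11 to 0.212. The count was 4 without H151 36 h, 2 without the 24 h and 3 without the 36 h library of pDNA with H151, and 30 without pDNA 12 h. The NF-kB list had a median of -1.81 (8 of 25 lower adjusted over the list alone; adjusted p = 1.81e-21, adjusted p = 0.341 with an estimated correlation). Without the 24 h pair 5 genes passed, all lower. They were CCL2 (-3.82 ± 0.40, adjusted p = 0.00798), PIM1 (-2.28 ± 0.29, 0.0255), the GTPase GBP2 (-2.15 ± 0.26, 0.0133), SOCS3 (-1.97 ± 0.24, 0.0133) and TNFAIP3, the A20 brake on NF-kB (-1.48 ± 0.20, 0.0263).

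**Figure D2:**
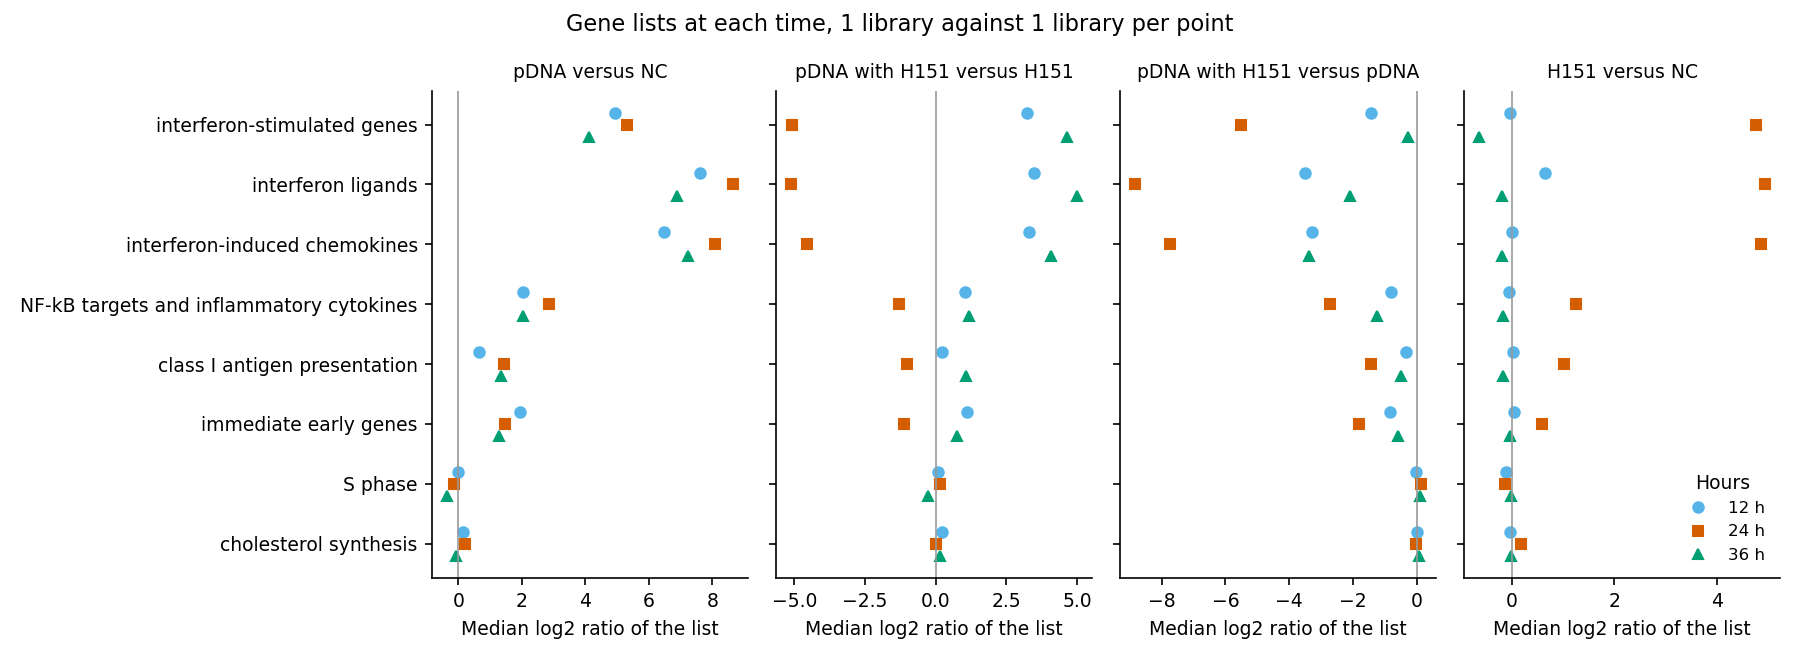
Median log2 ratio of 8 gene lists at 12, 24 and 36 h in 4 comparisons of the time course, each ratio from 1 library over 1 library. The interferon-stimulated list lies at 4.92, 5.32 and 4.13 in pDNA over NC and at 3.22, -5.08 and 4.65 in pDNA with H151 over H151, where the 24 h value comes from the libraries labelled pDNA_H151 24 h and H151 24 h.

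A trend of the pDNA effect with time, shared by both pDNA arms, was tested next. EdgeR called 0 genes (1677 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 90. A list is given here by the change of its pDNA effect, which can come from the pDNA libraries or from their controls. The effect on the replication-dependent histones, which package newly made DNA, declined by 0.42 per 12 h in the median, with all 14 members negative (12 adjusted over the list alone; adjusted p = 2.72e-13, adjusted p = 0.166 with an estimated correlation). Their median log2 ratio of pDNA over NC was -0.01, 0.10 and -0.89 at 12, 24 and 36 h, and with H151 it was 0.07, -0.04 and -0.72. H1-5, a linker histone, stood at 397 CPM in pDNA and 431 CPM in pDNA with H151 at 36 h, against 1120 in NC and 1045 in H151. RN7SL1, an abundant RNA without a poly(A) tail, took 10.3% of counts in pDNA 36 h, 6.34% in pDNA with H151 36 h and 6.94% to 8.72% in the other time-course libraries. The effect on the unfolded protein and integrated stress response list declined as well (median -0.54, adjusted p = 4.07e-08; 8 of 16 lower and 1 higher adjusted over the list alone; adjusted p = 0.166 with an estimated correlation), with ASNS, asparagine synthetase, at -1.69 ± 0.30 (adjusted p = 0.161). The level of this list rose in the controls, with a median log2 CPM of 5.852, 6.025 and 6.836 in NC and 6.107, 6.315 and 6.825 in H151 at 12, 24 and 36 h, against 6.180, 6.087 and 6.105 in pDNA and 6.201, 6.217 and 6.160 in pDNA with H151. Mitochondrially encoded mRNAs took only 0.0364% to 0.0601% of counts in the time-course libraries. Mitochondrial genes took a median of 4.26% of UMIs in the single cells, so the bulk values of this list rest on a small residue. The pDNA effect increased for mitochondrially encoded mRNAs (0.45, adjusted p = 3.2e-07), class II (0.42, 0.00177), class I (0.39, 6.35e-06), monocyte markers (0.39, 6.44e-05) and lysosome genes (0.15, 0.00066). It declined for S phase genes (-0.18, 1.25e-05, 20 of 20 negative), immediate early genes (-0.13, 0.00328) and p53 targets (-0.10, 0.0207). The immediate early list stood at 0.013, 1.101 and 2.544 in NC and at 2.448, 2.595 and 1.809 in pDNA by the same measure. With an estimated correlation the adjusted p of these 8 lists was 0.166 to 0.538. The gene count was 32 without H151 24 h, 87 without the 24 h and 140 without the 12 h library of pDNA with H151, and 12 and 259 without all libraries of 12 or 24 h. Without the 24 h pair it was 214 (54 higher, 160 lower), with 7 of 14 histones lower (adjusted p = 0.247 with an estimated correlation).

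Sorted GFP-positive cells, which translated the reporter, were compared with GFP-negative cells, both 12 h after transfection. Histone transcripts fell in GFP-positive cells, with 14 of 14 members of the list called (median log2 fold change -2.72, camera adjusted p = 5.18e-81, adjusted p = 0.711 with an estimated correlation). H1-5 (chromosome 6, 27866849 to 27867529) went from 1405 ± 576 CPM to 98.2 ± 19.3 CPM (SD, n = 2; log2 fold change -3.84 ± 0.42, adjusted p = 0.000262). H2BC13 fell by 4.16 ± 0.41 (adjusted p = 0.00024). CDK1, the kinase that drives entry into mitosis (chromosome 10, 60778331 to 60794852), fell by 2.53 ± 0.35 (adjusted p = 0.00106), UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, by 1.84 ± 0.36 (0.0294), and RRM2, a subunit of ribonucleotide reductase, by 1.73 ± 0.34 (0.0333). FAP, a membrane serine protease (chromosome 2, 162170684 to 162245151), rose from 0.702 ± 0.109 to 11.9 ± 0.918 CPM (SD, n = 2; 4.06 ± 0.52, adjusted p = 0.000565). PPP1R3C, a glycogen-targeting phosphatase subunit, rose by 3.84 ± 0.73 (0.0219). ZNF396 and FNDC7 had no count in GFP-negative cells and were at least 40-fold and 25.2-fold higher (adjusted p = 0.00397 and 0.0383). The sorted libraries held 21443 to 25604 genes with a count, against 27768 to 29809 in the time course. A missing count in a sorted library thus need not mean an absent transcript. In unsorted cells ZNF396 had 17, 20 and 22 counts in NC and 28, 35 and 18 in pDNA, so its bound is uncertain. In single cells with most EGFP, grouped further on, its share was 2.3 times that of cells with little (from 5 and 50 UMIs). That of FNDC7 was 23.6 times.

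In all, 80 of 16656 genes passed, 7 higher and 73 lower, each named one in the same direction in both same-numbered pairs. DESeq2 called 154 (23 higher) and limma-voom 104 (6 higher). S phase genes had a median of -0.95 (20 of 20 negative, 1 called, 14 adjusted over the list alone; adjusted p = 6.57e-17) and G2 and M phase genes of -0.59 (2 called, 6 over the list alone; 6.64e-10). Cholesterol synthesis (-0.42, 0 of 21 called, 0.000147) and heat shock (-0.30, 0 of 10 called, 2 over the list alone, 0.000882) were lower as lists. The adjusted p of these 4 lists was 0.746 with an estimated correlation. Interferon-stimulated genes were slightly lower (-0.18, 0 of 46 called, 35 negative, adjusted p = 0.015, adjusted p = 0.947 with an estimated correlation), but this rested on single libraries, since the median was -0.02 without GFP-negative 2, with 24 of 46 negative, -0.44 without GFP-negative 1 and -0.29 without GFP-positive 2. The median of G2 and M phase genes ran from -0.43 without GFP-positive 2 to -0.98 without GFP-positive 1, and that of cholesterol synthesis from -0.23 without GFP-negative 1 to -0.57 without GFP-negative 2. That of S phase genes ran from -0.80 to -1.37 and that of heat shock genes from -0.31 to -0.44 over the 4 fits without 1 library. IFNB1 stood at 169 ± 95.5 CPM in GFP-negative and 209 ± 56.7 CPM in GFP-positive cells (SD, n = 2; 0.31 ± 0.40, adjusted p = 0.975), and CXCL10 at 4235 ± 648 and 2509 ± 146 CPM (adjusted p = 0.743), so neither passed. Other lists not called were ligands (median -1.30, adjusted p = 0.187), chemokines (-0.53, 0.0897), NF-kB targets (0.16, 0.187), class I (-0.22, 0.187), class II (0.25, 0.22), mitochondrially encoded mRNAs (0.42, 0.166), stress response (0.10, 0.358), p53 targets (0.16, 0.487), inflammasome (0.03, 0.497), immediate early genes (0.00, 0.846), monocyte markers (-0.12, 0.846), lysosome genes (-0.13, 0.62), hypoxia (-0.18, 0.62), DNA sensing (-0.10, 0.764), translation restriction (0.11, 0.841), foreign DNA silencing (-0.02, 0.898) and markers of other cell types (0.11, 0.976). RN7SL1 took 23.1% of counts in GFP-negative replicate 1 and 12.3% to 14.8% in the other sorted libraries. The count was 138, 159, 148 and 127 without GFP-negative 1 or 2 or GFP-positive 1 or 2, of which 26, 53, 16 and 28 were higher. It was 95 with upper-quartile factors (13 higher) and 148 with no filter (28 higher). UBE2C did not pass without GFP-negative 1 (adjusted p = 0.0718), RRM2 without GFP-negative 2 (0.0739) or GFP-positive 2 (0.0739), and FNDC7 and PPP1R3C without GFP-positive 1 (0.515 and 0.162). The ranges over the alternatives were 9.07e-16 to 0.00185 for CDK1, 2.95e-14 to 0.0104 for FAP and 5.26e-26 to 0.00032 for H1-5.

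**Figure D3:**
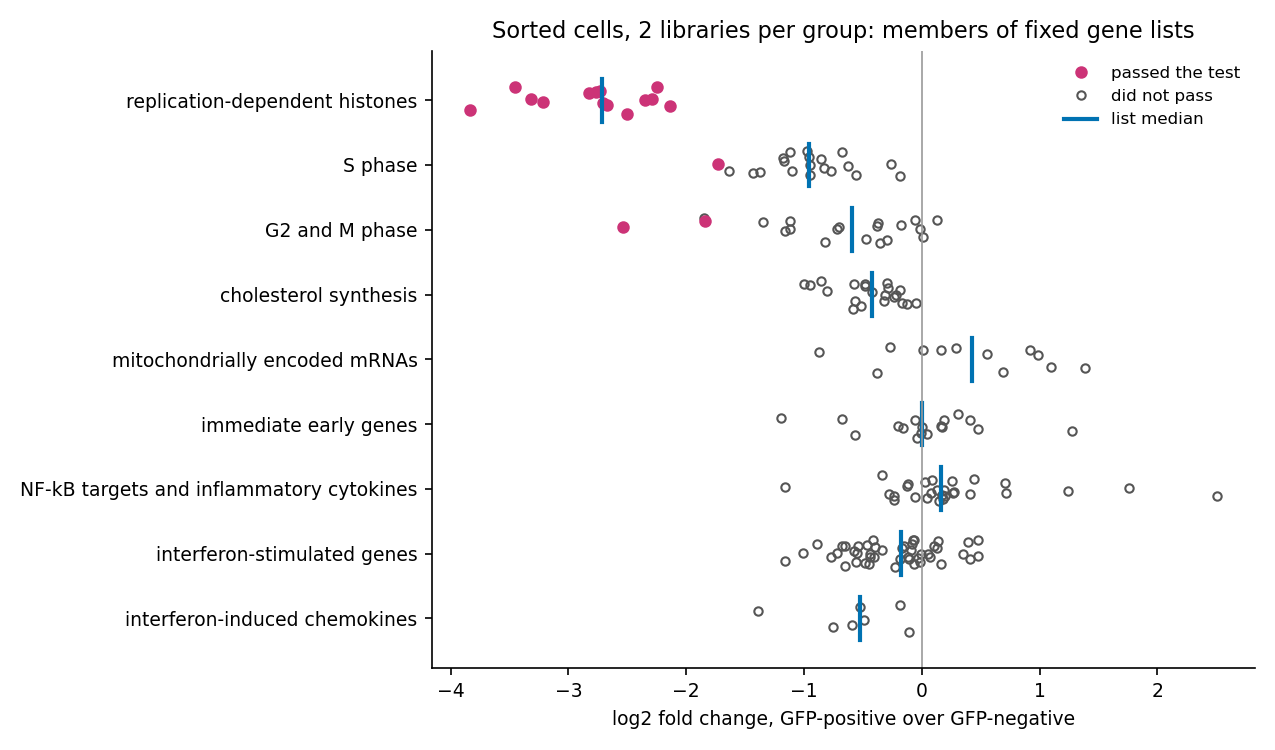
Log2 fold change of GFP-positive over GFP-negative sorted cells (horizontal axis) for the members of 9 gene lists, 1 point per gene and 2 libraries per group, filled where the gene passed the test. All 14 histone genes are filled, with a median of -2.72, and 0 of 46 interferon-stimulated genes are.

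The single-cell library described how the response was spread over cells at 12 h, with no test since it is 1 library. Shares of cells with a UMI were not corrected for free RNA. After thinning, ISG15 was detected in 98.8% of cells (unthinned 99%), CXCL10 in 92.7% (92.0 to 93.3; unthinned 98.0%) and MX1 in 90.8% (unthinned 92.5%). IFNB1 was detected in 17.7% (16.7 to 18.7; unthinned 28.8%) and IFNL1, a type III interferon, in 10.2% (9.44 to 11.1; unthinned 17.7%). In barcodes with fewer than 500 genes, which serve as background at a median of 731 UMIs against 28880, the shares were 88.6%, 80.9%, 26.1%, 12.5% and 6.76% in the same order. Their pooled level was 2820, 2034, 355, 188 and 90.6 CPM in these barcodes and 3509, 3890, 995, 159 and 159 CPM in cells. Per UMI these barcodes thus held ISG15 and IFNB1 at a level near that of cells. Damaged cells could give such levels as well as free RNA, so the exact share of cells that made these transcripts stays open. For the interferon ligands the clusters below bear on free RNA. The thinned share of cells with a UMI of STING1 was 18.2% (unthinned 48.7%, background 1.59%) and that of CGAS 62.9% (87.8%, 5.17%). The 61 cells with most IFNB1 UMIs held 35.0% of them, against 3.82% in Poisson draws, and for IFNL1 it was 48.7% against 3.85%. For MX1 it was 5.25% against 3.4% and for ISG15 6.85% against 3.32%.

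Clustering gave 8 groups of 3.07% to 24.9% of cells, none of which could be named from the fixed markers. The interferon ligands took 960 CPM in cluster 1, whose leading genes included NRG2, EXT1 and IFNL1, and 6.38 to 237 in the others. Free RNA alone would reach cells of like depth alike. Clusters 3, 5 and 7 held 6.38, 6.83 and 8 CPM of the ligands. Their median was 29932, 39603 and 33456 UMIs, against 34385 in cluster 1. These values argue against free RNA as the main source of the ligand UMIs in cluster 1. Cluster 3 was led by the S phase genes EXO1 and CCNE2, cluster 2 by HSPA1B and HMGCS1 at a median of 12531 UMIs, cluster 4 by CCL7 and CCL2, cluster 5 by GLDN and VCAN, cluster 6 by SPP1 and APOBEC3A, cluster 7 by TRPM1 and ALX1, and cluster 8 by EGFP and FAP. Fixed markers of cell types were mixed. Unthinned, the monocyte markers ran from 0.0163% of cells (FCN1) to 87.0% (MNDA), with LYZ in 79.8%, and the macrophage markers from 0.294% (MRC1) to 77.7% (CD68). Of the B cell markers PAX5 was detected in 72.7% and the other 4 in 0.0816% to 2.22%. Erythroid, T cell, epithelial and fibroblast markers were each in at most 1.01%.

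EGFP, the reporter, was detected in 82.5% of cells (81.5 to 83.5; thinned 38.5%) and in 71.9% of the background barcodes. Most of its UMIs lay in few cells. The 80 cells with 1000 or more EGFP UMIs, 1.31% of all (1.04 to 1.62), held 82.3% of EGFP UMIs, while the 3916 cells with 1 to 3 (63.9%) held 1.92%.

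**Figure D4:**
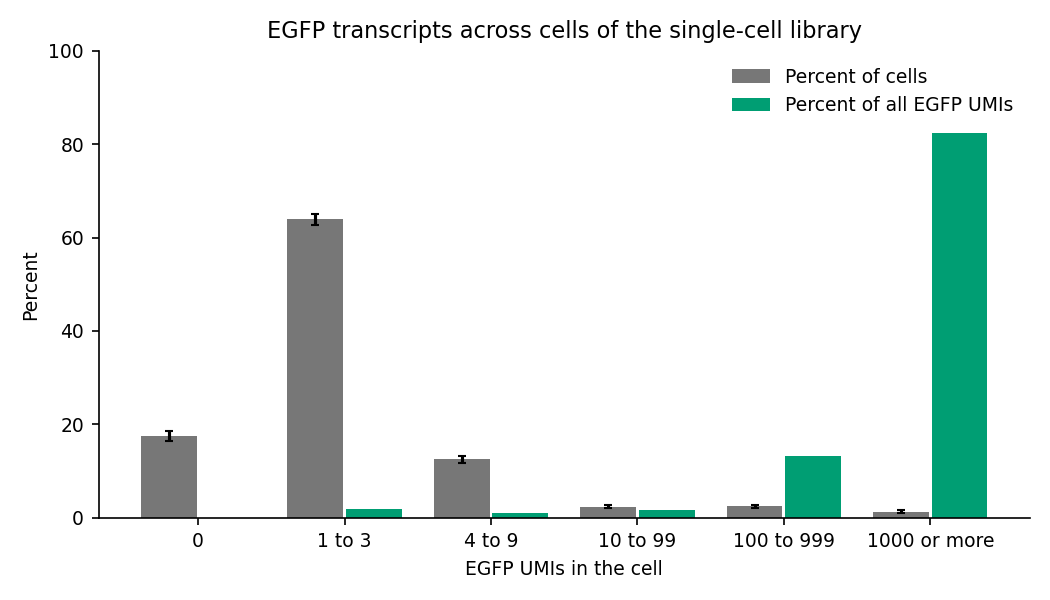
Percent of the 6128 kept cells (bars with exact binomial 95% intervals, counting error only) and percent of all EGFP UMIs, by the number of EGFP UMIs in a cell. Cells with 1000 or more UMIs are 1.31% of cells and hold 82.3% of EGFP UMIs.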

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

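The 3 tests on the 24 h libraries, the test on RNA without a poly(A) tail, the test on cells grouped at 100 and 10 EGFP UMIs and the fits without 24 h libraries were chosen only after the results were seen.

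A test of the difference between the pDNA responses with and without H151 called 1 gene of 19173, PIM1, with an interaction of -2.2 on the log2 scale. It did not pass when any 1 of the NC libraries, H151 12 h, pDNA 24 h or pDNA with H151 12 h was left out (adjusted p = 0.0541 to 0.161). Camera called 13 lists, and 0 with an estimated correlation. Chance could not be excluded for the gene count, with as many in 11 of 100 redrawn groupings. Their median interaction was -3.88 for interferon-stimulated genes, -7.87 for interferon ligands, -8.53 for chemokines, -1.81 for NF-kB targets, -2.09 for translation and foreign RNA restriction, -1.31 for immediate early genes, -1.08 for class I, -1.04 for monocyte markers, -0.83 for class II, -0.83 for inflammasome genes, -0.55 for lysosome genes, -0.21 for p53 targets and 0.16 for S phase genes. These medians include the libraries labelled H151 24 h and pDNA_H151 24 h. Without them the medians were smaller in size, at -0.575 for interferon-stimulated genes, -3.467 for ligands, -3.313 for chemokines, -1.241 for NF-kB targets, -0.213 for translation and foreign RNA restriction, -0.790 for immediate early genes, -0.529 for class I, -0.793 for monocyte markers, -0.634 for class II, -0.426 for inflammasome genes, -0.401 for lysosome genes and 0.074 for S phase genes, while p53 targets stood at -0.267. Then 5 genes and 13 lists were called, 0 lists with an estimated correlation. Of the 13 lists 12 were shared, and S phase genes (camera adjusted p = 0.13) were no longer called. The list gained was markers of other cell types, with 4 members tested (median -0.520, camera adjusted p = 0.0266, 0.423 with an estimated correlation). The IFIT1 interaction changed sign to 0.41.

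At 24 h the interferon-stimulated list ran against the other times, a difference that was not tested since each condition has 1 library per time. Its median log2 ratio was -5.08 in pDNA with H151 over H151, against 3.22 and 4.65 at 12 and 36 h, and 4.76 in H151 over NC, against -0.03 and -0.65. RNA carried over between libraries adds transcripts and takes none away, yet the list median of the library labelled pDNA_H151 24 h changed by -4.19 relative to the lower of the other libraries of that condition, which argues against carry-over as the whole cause. An exchange of the labels of the 2 libraries needs both to be out of place at once, and 100% of the 46 genes were. An opposite action of H151 at 24 h would look the same (the library labelled H151 24 h lay 4.80 above the mean of the other H151 libraries), so it cannot be told apart from an exchange with 1 library per condition and time. An exchange therefore may account for the pattern, and it remains a hypothesis found on the same data.

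Replication-dependent histone transcripts were lower in GFP-positive cells. No single sorted library set the difference, since the highest list median over the fits without 1 library was -2.38. A lower yield of RNA without a poly(A) tail would lower other such RNAs by about as much as the histones, but the 2 of 8 with enough counts, RN7SL1 (-0.57 ± 0.53) and SNORD3A (0.62 ± 0.44), had a median of 0.03, which argues against it, as far as 2 genes that moved apart can. In the sorted libraries the S phase list had a median log2 fold change of -0.95, with 20 of 20 members negative and 1 called. Whether a smaller share of GFP-positive cells was in S phase stays open. Cells ranked by EGFP cannot decide it, and the bound of 100 EGFP UMIs was chosen after the results were seen. In cells with 100 or more EGFP UMIs (median 27074 UMIs without EGFP) the S phase list took 0.53 of its share in cells with fewer than 10 (median 28939). For cells ranked by EGFP, the top 25% over the bottom 25%, the ratio was 0.813, between the bounds set beforehand, with a median of 16260 against 29991 UMIs. Among cells at or above the median UMIs it was 0.951, with a median of 5 EGFP UMIs in the top 25% and 1 in the bottom 25%. The histone list was lower in each of these comparisons, at 0.457 for cells with 100 or more EGFP UMIs, 0.531 for ranked cells and 0.788 for those at or above the median UMIs. H4C3 alone gave 496 of the 990 histone UMIs in cells with 100 or more and 31369 of 49800 in cells with fewer than 10. H2BC5, H2AC6 and H2BC21 went the other way (6.34, 3.47 and 1.7 times), and the other members with a UMI were lower. This summed share is thus not the same measure as the median over genes in the sort. The top 25% of all kept cells had a median of 4 EGFP UMIs. Both rankings thus hold many cells with little EGFP and cannot decide the question. A smaller share in S phase may therefore contribute, as a hypothesis only, and the sort itself and the amount of pDNA per cell were not tested.

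EGFP, a signal outside the bulk comparisons, was detected in 82.5% of kept cells and in 71.9% of barcodes with fewer than 500 genes, so detection alone does not set cells apart from background. Free EGFP RNA in the droplets may explain cells with a few UMIs, but the barcodes with fewer than 500 genes were not shown to be empty droplets. Damaged cells that hold EGFP could give the same values, which was not tested. EGFP took 411 times the share of UMIs in these barcodes that it took in the median kept cell. That ratio sets a pooled value (25381 CPM) over a median (61.8 CPM). The median such barcode had 25.3 times the share of the median kept cell, and pooled kept cells, few of which hold most EGFP, stood at 2042 CPM. The cells with 1 to 3 EGFP UMIs held 1.92% of all. The 10 low barcodes with most EGFP held 27.6% of the EGFP of such barcodes, and without them the level was 18694 CPM against 25381 CPM. No untransfected cells were measured, so a low true expression in part of these cells stays open and no biological explanation was tested.

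The 6 libraries of each comparison can be split in 10 ways, the real one included, too few for a share under 0.05. For pDNA versus NC the real grouping called 967 genes and the highest other 0 (1 split in all gave as many). For pDNA with H151 versus pDNA it called 6 against 69 (2 splits). The split with 69 mixes condition with time, which points to a structure of the samples, and among the 4 splits that part the libraries of every time, the real one included, the highest other was 0. For H151 versus NC it called 0 against 0. For pDNA with H151 versus H151 it called 0 against 905, and the split with 905 is the one that exchanges the 24 h libraries of the conditions, which points to a structure of these samples. For the interaction chance could not be excluded, with 1 gene in the real grouping, 72 in the highest other and as many in 11 of 100 redrawn groupings. Where the real grouping called 0, as for the trend (highest other 810), every split has as many by construction (10 of 10, and 100 of 100 for the trend), which says nothing on chance. What set the 810 was not examined.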

How the results depend on the processing

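The fits without the 24 h libraries labelled H151 and pDNA_H151 were chosen only after the results were seen. Except where the construction shows it (fewer libraries, fewer or more genes tested, a fold limit), the cause was not tested. Single-gene values were counted once per gene and setting. They kept their direction and side of the threshold 498 times for pDNA versus NC (284 weaker, 20 stronger) and 240 for GFP (15 weaker, 1 stronger, 2 reversed). The number was 188 for pDNA with H151 versus pDNA (47 weaker, 4 stronger) and 97 for the interaction (11 weaker, 2 reversed). It was 85 for H151 versus NC (9 reversed) and 74 for pDNA with H151 versus H151 (16 reversed, 6 stronger). In the last 2 comparisons 0 genes passed over all libraries, so the side kept there was not passing. Genes near 0 counts in NC, such as IL6, have ratios with wide intervals. Camera on ranks and RLE factors left the number of called lists within 1.5 times. Fry, which asks whether a list's genes moved on balance one way, gave for pDNA versus NC an adjusted p of 0.0468 for NF-kB targets and 0.0662 for interferon-stimulated genes, and for GFP 0.368 for histones.

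DESeq2 called 2797 genes for pDNA versus NC, 476 for pDNA with H151 versus pDNA, 3 for H151 versus NC, 148 for the interaction, 90 for the trend and 154 for GFP. Limma-voom called 0 in the interaction. With no filter the counts were 1559 for pDNA versus NC, 158 for pDNA with H151 versus pDNA, 28 for the interaction, 69 for the trend and 148 for GFP. The filter at 5 CPM gave 0 for the interaction and 131 for GFP. A fold limit left 438 genes for pDNA versus NC. With no time term pDNA versus NC had 413, and CXCL10 in pDNA with H151 versus H151 went to -0.30. The fit of 6 libraries gave 2384 for pDNA versus NC and 0 for pDNA with H151 versus pDNA. The fit of all 16 libraries gave 1065 for GFP.

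Leaving out a library or time moved the count between 3 and 2905 for pDNA versus NC, 0 and 222 for pDNA with H151 versus H151, 1 and 345 for pDNA with H151 versus pDNA, 0 and 30 for the interaction, 0 and 259 for the trend, and 127 and 159 for GFP. The 222 and 259 came without all 24 h libraries, the 2905 without pDNA_H151 24 h, the 345 and 30 without pDNA 12 h, the 3 without NC 24 h. The ranges of log2 fold changes that follow are over all alternatives, the fit without the 24 h pair included. In pDNA with H151 versus H151 they ran from -0.61 to 4.97 for IFNB1 and from -0.73 to 8.16 for CXCL10. IFIT1 ran there from -0.89 to 7.80 and ISG15 from -1.49 to 5.01. In H151 versus NC they ran from -1.59 to 6.81 for CXCL10, from -1.96 to 6.91 for IFIT1 and from -0.54 to 4.87 for ISG15. The interaction of IFIT1 ran from -9.40 to 0.75, and IFNB1 in GFP-positive cells from -0.18 to 0.99.

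Without the pair of 24 h libraries the counts were 3247 for pDNA versus NC, 255 for pDNA with H151 versus H151, 67 for pDNA with H151 versus pDNA, 5 for the interaction and 214 for the trend. H151 versus NC then gave -1.09 for CXCL10, -1.63 for IFIT1 and -0.25 for ISG15, and the IFIT1 interaction was 0.41. Camera then called 17 lists for pDNA with H151 versus H151 and 3 for H151 versus NC. With an estimated correlation it called 0 lists in each of the 7 comparisons over all libraries. Without the pair it called 7 for pDNA versus NC, 6 for pDNA with H151 versus H151, 5 for pDNA with H151 versus pDNA, and 0 for H151 versus NC, the interaction and the trend.

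The sorted replicates share numbers, but the labels do not say that a number marks a shared culture, and with 2 pairs the pairing correlation was 0.187. With the replicate number as a block the count was 455, of which 304 were lower.

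In single cells the thinned share with IFNB1, 17.7% as reported, was 16% at 200 genes or more, 19% at 1000, 20.5% at 10% mitochondrial UMIs or less, 15.9% with no such limit and 25% when thinned to the 25th percentile, which is deeper. CXCL10 (92.7%) went to 90.2%, 94.4%, 95.7%, 90.6% and 97.7% and ISG15 (98.8%) to 98%, 99.3%, 99.6%, 97.9% and 99.9% in the same order. IFNL1 (10.2%) went to 11.3% at 1000 genes, 12.3% at 10% mitochondrial UMIs and 15.4% at the 25th percentile. The top 5% of cells held 75.6% of IFNB1 UMIs. Resolution 0.3 gave 5 clusters and 1.0 gave 16, with largest clusters of 43.2% and 11.5%. The largest cluster held 20.6% with 1000 variable genes and 26.8% without the cell called a doublet.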

Other observations

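The groups of single cells by EGFP UMIs, their second bound at 10 UMIs and the fits without 24 h libraries were chosen only after the results were seen.

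Cells with the most reporter RNA differed in part of the response from the others. The 229 cells with 100 or more EGFP UMIs (3.74%) were set beside the 5752 cells with fewer than 10. Immediate early genes took 1.47 times the share of UMIs in the former (1.27 with a bound of 10 UMIs), IL1B 2.53 times (1.78) and CXCL8, a neutrophil chemoattractant, 2.17 times (1.59), but the list of NF-kB targets and inflammatory cytokines as a whole took 1.03 times (0.896), TNF 1.27 times (1.11) and IL6 0.933 times (0.813), so no rise of inflammatory genes as a group is shown. Interferon-stimulated genes took 0.817 times (0.825), chemokines 0.751 times (0.744) and RRM2 0.298 times the share. After thinning, IFNB1 was detected in 19.1% of the former (14 to 25; unthinned 37.6%) and 17.2% of the latter (16.2 to 18.3; unthinned 28.2%), where the intervals overlap. In the 376 cells with 10 or more EGFP UMIs it was 23.7% (19.3 to 28.6), which lies above the interval of the cells with fewer than 10, so the reading depends on the bound. Of 58 genes lower in sorted GFP-positive cells with 100 or more UMIs here, 49 were also lower in EGFP-high cells (median ratio 0.427), and 5 of 5 genes higher in the sort were also higher (median ratio 11.6). SNX31 (17.0 times), FNDC7 (23.6 times) and FAP (9.98 times) were among them. The replication-dependent histone list took 0.457 times the share (0.382 with a bound of 10 UMIs), where H4C3 alone gave 496 of its 990 UMIs in the former cells. Not all histone genes were lower, with H2BC5 at 6.34 times and H2AC6 at 3.47 times, against H4C3 at 0.363 and H1-5 at 0.289. These are values of 1 library, with no test. The library pools cells given 2 µg and 4 µg pDNA with no map to cells, so EGFP level and pDNA amount cannot be told apart. The groups also mix unlike clusters. EGFP was highest in cluster 8 (38128 CPM) and cluster 6 (2894 CPM), where the NF-kB list took 2890 and 9435 CPM.

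Across 5515 thinned cells, the score of interferon-stimulated genes moved with that of translation and foreign RNA restriction genes (Spearman 0.816, where the lists share IFIT and OAS members). It also moved with p53 targets and apoptosis genes (0.666), chemokines (0.641) and class I genes (0.582), and against heat shock genes (-0.382). The p53 list holds apoptosis genes such as FAS and TNFSF10, so its score need not show p53 activity. The median over 253 pairs of lists was 0.0176. Cells are not replicates, so these describe this library only. In the fit without the 24 h pair, NPC1, a lysosomal cholesterol exporter, was lower in pDNA with H151 than in pDNA (-0.76 ± 0.13, adjusted p = 0.0296). CNR1 fell in pDNA with H151 relative to H151 (-0.96 ± 0.19, adjusted p = 0.0282), as did SELPLG, a selectin ligand (-0.78 ± 0.17), and MAP2K6, a p38 kinase activator (-1.16 ± 0.22).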
